A study of Caenorhabditis elegans with 2 samples.

How the data were processed

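The data were chromatin immunoprecipitation sequencing (ChIP-seq) of a tagged protein in whole Caenorhabditis elegans at the L4 larval stage. The worms, strain OP692, carried an integrated transgene that expresses T26A8.4 fused to enhanced green fluorescent protein, together with an unc-119 rescue copy in an unc-119 mutant background. Chromatin was fragmented by sonication and precipitated with an antibody against GFP, per the labels. The larvae were 48 hours old and had been synchronised by bleaching and L1 starvation. The series has 1 group of 2 libraries, which the labels call separate biological replicates. It has no contrast between conditions, so the comparisons were between the replicates, and between peaks and random positions, gene lists, gene types and DNA sequences.

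The deposited files were 8 peak lists on the ce11 build, which is the same assembly as WBcel235, per the file listings that accompany the samples. For each replicate there was a list of ranked peaks and a thresholded list, and for the replicates together there were 2 ranked lists, a thresholded list (called the combined set here) and a conservative thresholded list. Thresholding was on the irreproducible discovery rate (IDR), a measure of how well the ranks of a peak agree between 2 inputs, per the file listings. Each peak has an integer score up to a maximum set by the authors' software and a peak signal, which is also a score and whose scale is not given in the sources used here. Both are the authors' own deposited values and were used to rank or filter peaks within a list. The deposited lists also give a q-value as −log10, and the ranked lists give the IDR as −log10. The aligner, the peak caller and their versions are not given in the sources used here. A control library is named as a possible control in the labels and was not used here. Read depths are not in the peak lists, so the depth behind each peak is unknown. Each thresholded list held the lines of its ranked list with a score of at least 830, where −log10 of the IDR was about 2.0, apart from a few lines that are described in the closing section. The series-level ranked lists hold 16 further columns with per-input values that no label ties to a replicate, and these were not used.

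Peak summits were placed on the RefSeq WBcel235 sequence and the Ensembl release 115 gene annotation. A promoter window ran from 1000 bp upstream to 200 bp downstream of the annotated start of a protein-coding gene, and a gene was called bound when a summit of the combined set lay in its window. Annotated gene starts in worms are often the sites of trans-splicing, which joins a leader to the transcript downstream of where transcription begins. Summits were compared with 1000 random placements on the same chromosomes, and the smallest two-sided p that these can give is 0.0020. Peaks of the 2 replicates were called shared when they overlapped by at least 50% of the shorter one. Permutation tests used 100000 resamples, and the smallest p they can give is 1e-05. Chromosome shares were tested with two-sided exact binomial tests, and gene lists, gene types and motifs with two-sided Fisher's exact tests, each family adjusted by the Benjamini-Hochberg method at 0.05. Gene lists (29) and motifs (19), the tests, the windows and the rule for named genes were fixed before the data were examined. Intervals are 95% Wilson intervals for shares, exact intervals for chromosome ratios and Woolf intervals for odds ratios. They cover counting error only, and peaks and genes are not independent replicates.

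Sequences were taken from 201 bp centred on each summit. Control windows, 5 per summit, lay at the same distance from the start of unbound protein-coding genes and over 500 bp from any summit. GC content was also compared with windows 500 to 700 bp away on both sides. Windows of 20 kb around T26A8.4 and unc-119 were compared with 10000 random windows of the same size. The genes named were T26A8.4 and unc-119, the genes at the 15 highest-signal combined peaks that overlap a thresholded peak of both replicates (the promoter gene, or else the nearest gene), the 3 bound members with the highest signal in each list that passed the test, the strongest bound member of other lists, and the 2 strongest bound members of each gene type that passed. Any other gene is said to have been chosen after its values were seen.

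The alternatives tried were the conservative set, the 50% of combined peaks with the highest signal, each replicate's own thresholded set, other promoter windows, only the nearest gene of each summit, a logistic model with upstream intergenic length, other overlap rules, other expected shares and other control windows. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and Matplotlib 3.10.9. The scripts were tested on simulated data. A planted promoter share of 40.0% was recovered as 40.0%, and a planted replicate overlap of 65.0% as 66.9%. In 20 simulations on 19973 protein-coding genes, 100% of 3 planted gene lists were called, and 0.577% of lists with nothing planted. A motif planted in 20% of windows was recovered in 19.2% more windows than before, and with nothing planted 0 motifs and 0 6-mers were called.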

Results

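The binding of T26A8.4, annotated as a protein with a C3H1-type zinc finger domain, was mapped in whole L4 larvae by ChIP-seq of a GFP-tagged copy. The 2 biological replicates formed 1 group, so the design asks where the protein was bound and how far the replicates agreed. The combined thresholded set held 2993 summits in 2856 distinct intervals, with a median width of 420 bp and 1.07% of the genome covered. The conservative set held 2810 summits, replicate 1 alone 1933 and replicate 2 alone 2141. The ranked lists, which include weak regions, held 66732 to 70405 peaks each. Peak signal is the authors' score and is compared within a list only.

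Most strong peaks were found in both replicates. Of the replicate 1 peaks, 1298 of 1933 (67.1%, 95% interval 65 to 69.2) were shared with replicate 2, and 1323 of 2141 replicate 2 peaks (61.8%, 59.7 to 63.8) were shared with replicate 1. Random placement gave 0.931% and 0.841% (permutation p = 0.0020 for both, the smallest these placements can give). Random members of the ranked list of replicate 2, a chance level chosen after the data were examined, gave 3.53% for replicate 1 peaks. Sharing fell with signal. In replicate 1 it was 96.5%, 79.5%, 58.8% and 33.7% from the strongest to the weakest quartile, and in replicate 2 it was 94.4%, 77.8%, 45% and 29.9%. Across 2743 combined-set summits present in both ranked lists, the peak signals of the replicates had a Spearman rho of 0.64 (permutation p = 1e-05, the smallest possible, across regions, which are not independent). Within quartiles of combined signal, rho was 0.74 in the strongest and −0.12, −0.44 and −0.31 in the others. Selection of peaks on their combined signal restricts these values. Of the combined peaks, 1345 (44.9%) overlapped thresholded peaks of both replicates and 740 (24.7%) of neither.

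**Figure D1:**
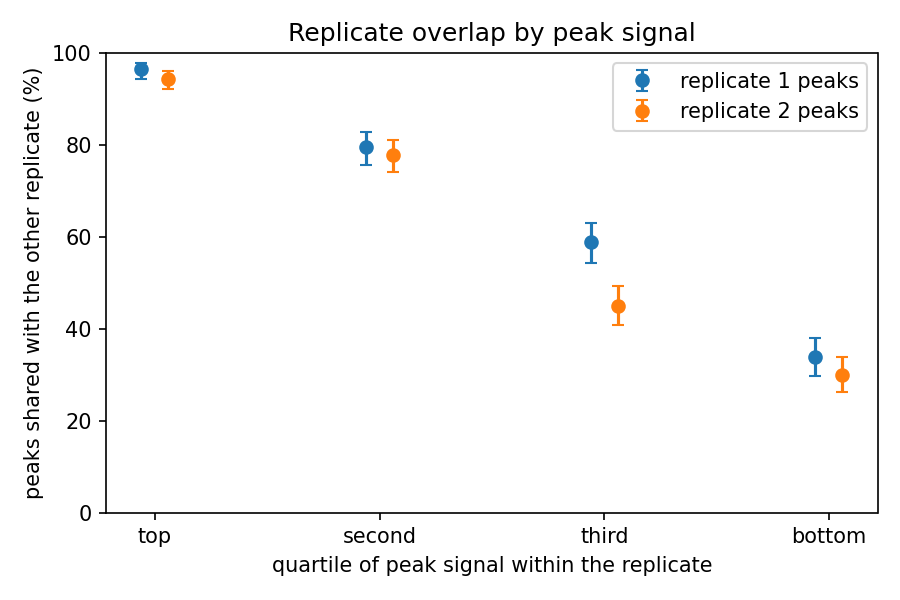
Percent of each replicate's thresholded peaks shared with the other replicate, by quartile of peak signal within the replicate (points, with 95% Wilson intervals). Sharing is 96.5% and 94.4% in the strongest quartiles and 33.7% and 29.9% in the weakest.

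The summits were concentrated near the starts of genes. A promoter window held 1221 summits (40.8%, 39.0 to 42.6), against 21.2% of randomly placed summits, a ratio of 1.93 (permutation p = 0.0020). Noncoding genes outside promoters held 4.68% of summits, 1.44 times the random share. Coding exons held 10.7% (ratio 0.539), introns 20.8% (0.675) and intergenic sequence 19.4% (0.900), all below random (permutation adjusted p = 0.0035 for the first 2 and 0.0084 for intergenic). The shares in 5′ untranslated regions (1.00%) and 3′ untranslated regions (2.57%) did not pass the test (permutation adjusted p = 0.389 and 0.613). The intergenic call was lost in the conservative set (ratio 0.933) and in the 50% of peaks with the highest signal (0.905). In that high-signal set the coding exon ratio was 0.276, and the 3′ untranslated share was below random, at a ratio of 0.442.

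The highest peak of the combined set lay on chromosome III, from 3867316 to 3867745 on WBcel235, with its summit at −292 bp from the start of rpl-3, which encodes a large ribosomal subunit protein. Its signal was 1884, and the replicates' own lists gave 869 and 1021. A peak at IV 4749914 to 4750243 (signal 1387) lay between the starts of rpl-20, another ribosomal protein gene, and Y17G9B.5. A peak at III 10759082 to 10759440 (1320) had its summit at −55 bp from the start of tasp-1 and −730 bp from that of K01G5.10. Peaks upstream of H41C03.3 (II, 1217) and egg-5 (I, 1159) covered sls-2.1 and sls-2.4, annotated as snRNA genes, with summits at −23 bp from the start of the first and +152 bp from that of the second. A peak of signal 1238 lay at IV 4725436 to 4725785, outside promoter windows, at +748 bp from the start of K08F11.1.

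The other 9 of these 15 peaks lay on X. Only the peak at 14525489 to 14526317 was in a promoter window, at −702 bp from the start of nspc-17 (signal 1552). Peaks lay in introns of mom-1 (6296284 to 6296895, 1525), which encodes a porcupine homologue needed for Wnt secretion, and of Y41G9A.17 (2996804 to 2997415, 1208). The remaining 6 were intergenic. Their nearest protein-coding genes were W02H3.3 (11093869 to 11094475, 1594), hpk-1 (4208941 to 4209599, 1503), adm-2 (13700614 to 13701140, 1304), ZK899.6 (9465625 to 9466165, 1217), C34D10.1 (8036086 to 8036920, 1195) and T27A8.7 (16056198 to 16056977, 1143). The peak near C34D10.1 covered the ncRNA gene C18A11.13 and the tRNA gene WBGene00022939.

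Chromosome X held 554 summits (18.5%), 1.05 times its share of genome length (0.970 to 1.13, exact binomial adjusted p = 0.277). Against its share of protein-coding gene starts the ratio was 1.35 (exact binomial p = 1.81e-13). That baseline does not count tRNA genes, of which X held 276 of 612. A summit lay in the same window of 132 of these, counted after the peak locations were seen. Among the 25 highest-signal peaks, 12 lay on X (48%, exact interval 27.8 to 68.7, exact binomial p = 0.00049), 11 of them outside promoter windows. Among the 100 highest, 23 lay on X, which did not pass (exact binomial p = 0.188). Both of these counts were chosen after the data were examined. Chromosome III held 1.33 times its length share (1.23 to 1.44, exact binomial adjusted p = 9.56e-12). Chromosomes V (0.753, exact binomial adjusted p = 4.64e-12) and IV (0.881, adjusted p = 0.0052) held less, and I and II did not pass. On the autosomes 1489 of 2439 summits (61.0%) lay in the middle 50% of the chromosome, a ratio of 1.22 by length and 1.10 by gene starts (exact binomial p = 7.56e-28 and 8.10e-08).

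**Figure D2:**
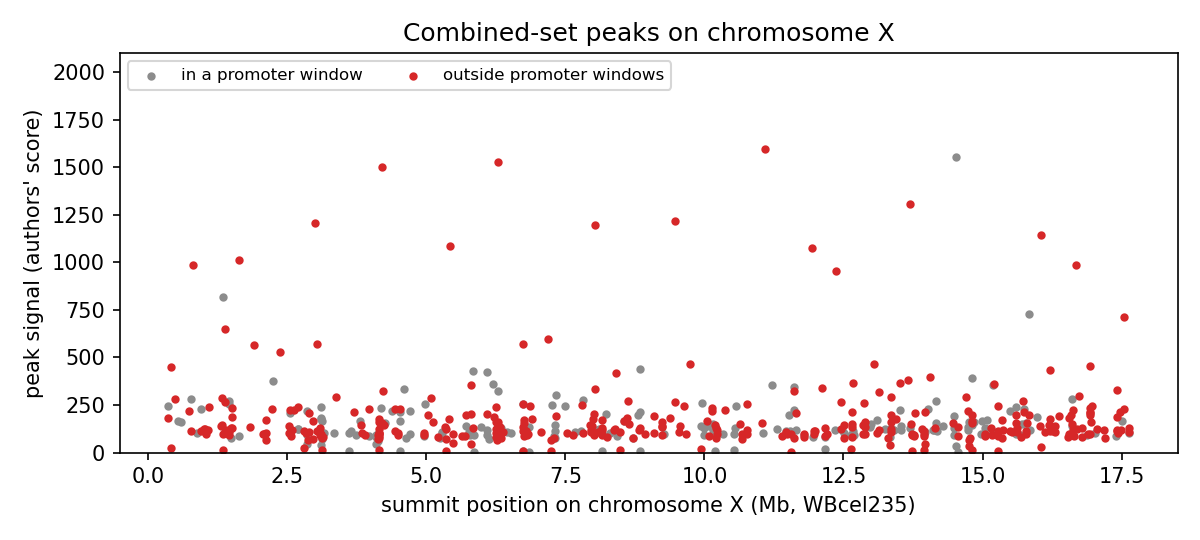
Signal of each combined-set peak (the authors' score) against summit position on chromosome X in Mb, with peaks in promoter windows in grey and others in red. Of the 12 X peaks among the 25 highest signals of the genome, 11 lie outside promoter windows.

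Strong peaks were in promoters more often than weak ones, and X differed from the autosomes in this. Over all chromosomes the promoter share was 50.3% in the strongest quartile of signal and 34.2% in the weakest, a difference of 16.1 percentage points (permutation p = 1e-05, the smallest possible). On the autosomes it fell from 54.8% to 33.8%. On X it was 33.1% in the strongest and 35.5% in the weakest quartile (permutation p = 0.707). The odds ratio of a promoter location, strongest against weakest quartile, was 2.37 on autosomes and 0.898 on X. The ratio of these odds ratios was 2.64 (1.52 to 4.56), a comparison chosen after the data were examined. In total 34.5% of X summits and 42.2% of autosomal summits lay in promoter windows (odds ratio 0.720, Fisher's exact p = 0.00080). Random placement gave 17.6% on X and 22% on autosomes, so both shares stood at about 1.9 to 2.0 times random.

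**Figure D3:**
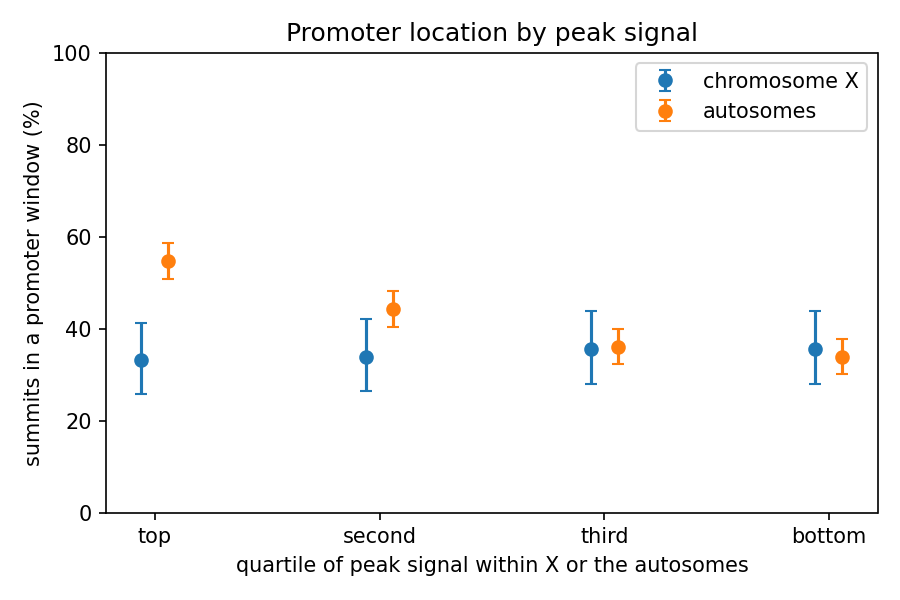
Percent of combined-set summits in a promoter window by quartile of peak signal, separately for X and the autosomes (points, with 95% Wilson intervals). The autosomal share falls from 54.8% to 33.8%, and the X share is 33.1% in the top and 35.5% in the bottom quartile.

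A summit lay in the promoter window of 1410 protein-coding genes (7.06% of 19973). Of the 29 gene lists, 10 were bound more often than other protein-coding genes, 4 less often, and 15 did not pass. Cytosolic ribosomal protein genes stood highest, with 47 of 81 bound (58.0%, odds ratio 18.8, 12 to 29.3, Fisher's exact adjusted p = 7.91e-32). With only the nearest gene of each summit their odds ratio was 10.1. Their strongest members were rpl-3, rpl-20 and rpl-35 (signal 1100), and the median offset of the nearest summit from the gene start was −294 bp. Translation factors had 12 of 41 bound (odds ratio 5.49), led by iff-2 (initiation factor 5A, signal 624), eif-3.C (589) and eef-2 (elongation factor 2, 462). Mitochondrial electron transport and ATP synthase genes had 12 of 37 (odds ratio 6.36), led by cox-5A (1077), atp-1 (563) and cox-6A (431). Mitochondrial ribosomal protein genes had 12 of 70 (odds ratio 2.74, Fisher's exact adjusted p = 0.0082), led by mrpl-28 (319), mrpl-12 (246) and mrps-21 (222). This last call was lost in replicate 2's own set (odds ratio 1.61), in the 50% of peaks with the highest signal (2.35) and with the narrower promoter window (2.38).

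Heterochronic genes, which time larval development, had 8 of 17 bound (odds ratio 11.8, 4.53 to 30.5), led by nhl-2 (signal 777), din-1 (285) and ain-1 (283). Its odds ratio was 5.31 in replicate 2's own set and 8.23 in replicate 1's, and the call was lost with the narrower promoter window (odds ratio 3.95, Fisher's exact adjusted p = 0.0875). Heat shock and chaperone genes had 14 of 60 (odds ratio 4.04), led by cct-8 (991), hsp-60 (793) and dnj-13 (586). Their odds ratio was 7.25 in replicate 1's own set, and with only the nearest gene of each summit it was 1.87 and did not pass. Chromatin and dosage compensation genes had 12 of 53 (3.88), led by cbp-1 (972), a histone acetyltransferase, set-4 (262) and mrg-1 (261). Cell cycle and DNA replication genes had 14 of 85 (2.61), led by cdc-48.1 (1056), rpa-2 (976) and pcn-1 (347), the sliding clamp of replication. CCR4-NOT and mRNA decay genes had 9 of 44 (3.40, Fisher's exact adjusted p = 0.0082), led by ntl-11 (690), ntl-2 (322) and cgh-1 (162). Actin and tubulin genes had 5 of 21 (4.13, Fisher's exact adjusted p = 0.0305), led by tba-2 (491), tbg-1 (222) and tbb-1 (151). Neither of the last 2 lists passed in either replicate's own set, with odds ratios of 2.53 and 2.21 for CCR4-NOT and 3.28 and 2.87 for actin and tubulin in replicates 1 and 2. Both were also lost in the high-signal set, in the narrower window and with the nearest gene only, and actin and tubulin genes in the conservative set (3.32).

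Genes of sensory and immune families were bound less often. Chemoreceptor genes had 11 of 1364 bound (odds ratio 0.100, 0.0551 to 0.181, Fisher's exact adjusted p = 2.13e-29), the strongest being srh-269 (signal 352), sri-5 (310) and srh-2 (298). F-box genes had 7 of 412 (0.224), with fbxb-72 (450), fbxb-85 (412) and fbxa-83 (303). Innate immunity genes had 9 of 358 (0.335, and 0.117 in the conservative set), with clec-57 (247), clec-126 (207) and spp-2 (144). Neuropeptide genes had 3 of 140 (0.287, Fisher's exact adjusted p = 0.0392), which were ins-39 (817), nlp-26 and flp-23 (79.2). The peak of nlp-26 was in replicate 2's own thresholded set only, and that of flp-23 in replicate 1's only. The neuropeptide call was lost in both replicates' own sets (odds ratios 0.283 and 0.248), in the model with intergenic length (0.349) and with the nearest gene only (0.366). It passed in the conservative set (0.101), the high-signal set (0.150) and the narrower window (0.131). Among the lists that did not pass, 0 of 50 neuronal genes and 0 of 34 molting and epidermal genes were bound. By an approximate rule, 3 divided by the number of genes, a count of 0 allows shares of up to 6% and 8.82%. Of other genes, 7.08% and 7.07% were bound, and neither list passed as less often bound (Fisher's exact adjusted p = 0.0781 and 0.226). The odds ratio interval for neuronal genes was 0.00801 to 2.11. Intestinal genes had 1 of 33 (mtl-1), body wall muscle genes 3 of 40 (cpn-3), cuticle collagens 9 of 175 (col-63), germline and meiosis genes 5 of 70 (syp-4) and sperm genes 2 of 88 (spe-46). The peak of mtl-1 was in neither replicate's own thresholded set, that of col-63 in replicate 1's only and that of spe-46 in replicate 2's only. Proteasome subunits had 6 of 33 (rpn-3, Fisher's exact adjusted p = 0.0506) and histones 10 of 72 (his-37, adjusted p = 0.0586). Both passed in each replicate's own set, the conservative set, the high-signal set and the wider window. Proteasome subunits also passed with the nearest gene only and with 1 summit per interval, and histones did not. Neither passed in the narrower window or in the model with intergenic length. Nuclear hormone receptors had 16 of 274 (nhr-47), homeobox genes 3 of 91 (ceh-38), detoxification genes 7 of 215 (haf-3, odds ratio 0.440), spliceosome and snRNP genes 5 of 34 (snr-4, 2.27) and aminoacyl-tRNA synthetases 2 of 32 (ears-2). Detoxification genes passed as less often bound in the conservative set (0.333), the high-signal set (0.295), replicate 1's own set (0.276) and the narrower window (0.258). Spliceosome genes passed as more often bound in the high-signal set (3.64) and replicate 1's own set (3.40). Vulva and gonad signalling genes had 7 of 50 (lin-54, odds ratio 2.15, Fisher's exact adjusted p = 0.127). The list passed in each replicate's own set (odds ratios 3.22 and 2.81), in the narrower window (3.00) and in the model with intergenic length (2.60). Its 7 bound members, named after their values were seen, were lin-54, lin-9, lin-53, lin-35, lin-36, lin-52 and sys-1.

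**Figure D4:**
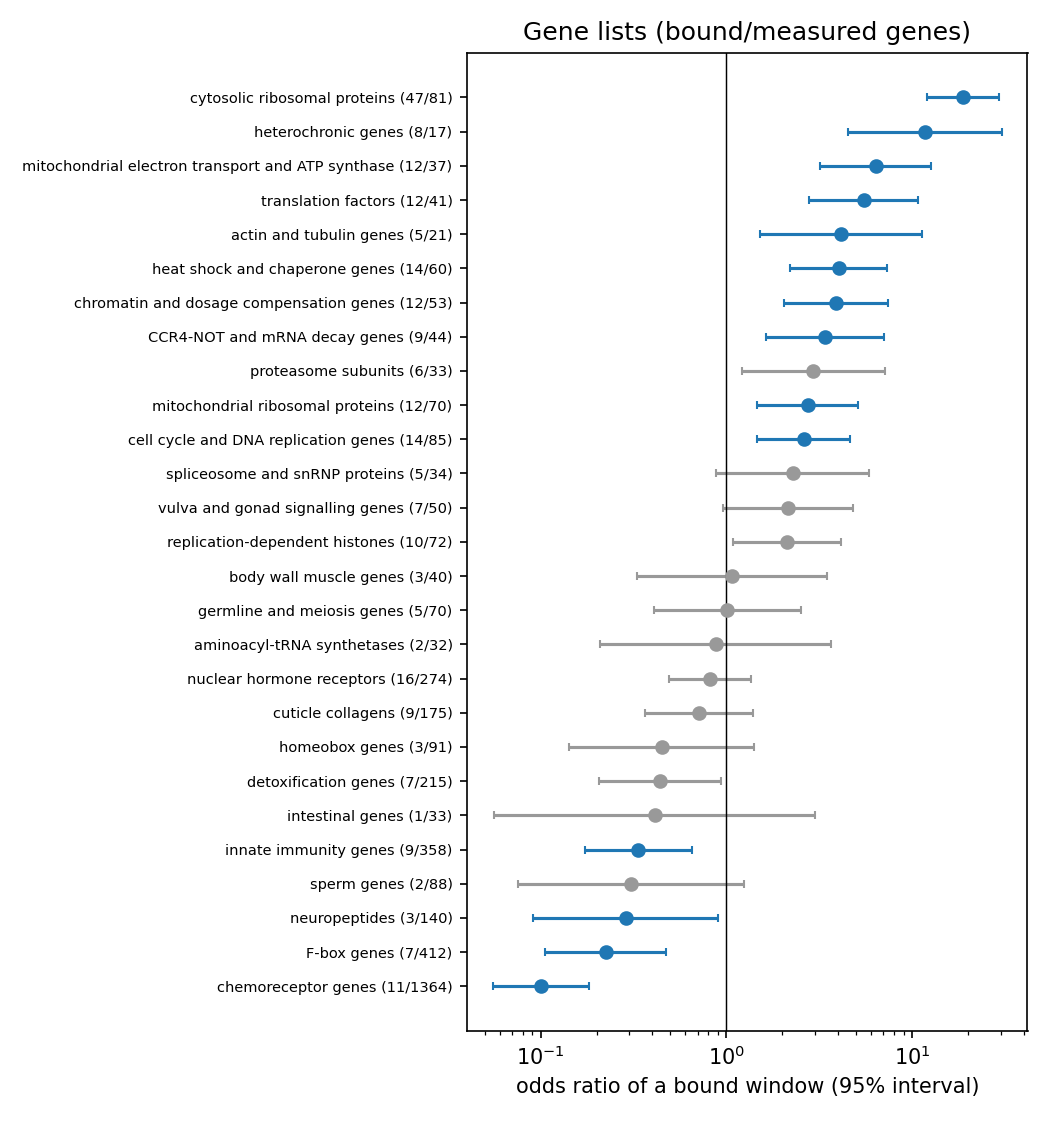
Odds ratio of a bound promoter window for each gene list with at least 1 bound member, against other protein-coding genes (points, log axis, bars are 95% intervals, blue where the adjusted p passes 0.05). Cytosolic ribosomal protein genes have an odds ratio of 18.8 and chemoreceptor genes 0.100.

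Genes for tRNA, snoRNA and snRNA were bound far more often than protein-coding genes. A summit lay in the window of 307 of 612 tRNA genes (50.2%, odds ratio 13.3, 11.2 to 15.7, Fisher's exact adjusted p = 1.00e-169), 32.4% of 346 snoRNA genes (6.30) and 36 of 129 snRNA genes (27.9%, 5.1). The nearest summit had a median offset of +10 bp from the start of bound tRNA genes and −44.5 bp from that of snoRNA genes. Within 200 bp of the gene there were 254 summits at tRNA genes, 30.3 times the random mean, 90 at snoRNA genes (16.2 times) and 50 at snRNA genes (27.5 times). The 2 strongest snRNA windows were those of sls-2.1 and sls-2.4. The strongest snoRNA windows were those of T27A8.8 and C06A1.9, with summits at −762 bp and −508 bp from their starts. The peak counted for T27A8.8 is the X peak named above for T27A8.7, and C06A1.9 shares its peak with cdc-48.1. The peak counted for the tRNA gene WBGene00023221 had its summit at −914 bp from its start, and that for WBGene00023111 at −98 bp. Other noncoding RNA genes had 648 of 7764 bound (8.35%, odds ratio 1.2, Fisher's exact adjusted p = 0.00048), led by WBGene00195021 and C18A11.13. That call was lost with the narrower promoter window (1.11) and turned to 0.878 with only the nearest gene of each summit. The piRNA genes had 117 of 15363 (0.762%, odds ratio 0.101) and pseudogenes 45 of 2128 (2.11%, 0.284), both below protein-coding genes. Their strongest windows were those of 21ur-13616 and 21ur-12279, and of WBGene00023323 and WBGene00017287. The summits counted for both piRNA genes also lay in protein-coding promoter windows, and that of 21ur-12279 belongs to the peak named above for atp-1. lincRNA, antisense RNA and rRNA genes did not pass, nor did miRNA genes (odds ratio 1.46), which passed in each replicate's own set (1.81 and 1.66) and in the wider window (1.55). The rRNA count, 0 of 20, was made without the past-threshold peaks at rrn-4.2 that the combined set leaves out. A total of 1475 summits (49.3%) lay neither in a protein-coding promoter window nor within 200 bp of a tRNA, snoRNA or snRNA gene.

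The bound sequence was richer in G and C than its surroundings. Summit windows had 43.8% GC and windows on both sides 37.0%, a difference of 6.85 percentage points (6.51 to 7.19, sign-flip permutation p = 1e-05, the smallest possible), with 75.4% of summits higher. Control windows at unbound gene starts had 35.3%. Of the 19 fixed motifs, 8 were more frequent than in control windows and 8 less. The GAGA repeat was in 30.5% of summit windows against 10.5% of controls (odds ratio 3.74, Fisher's exact adjusted p = 1.63e-152). The tRNA B box, an internal promoter element of tRNA genes, was in 5.95% against 0.207% (odds ratio 30.5). The AC repeat had an odds ratio of 6.40, the SP1 site 2.94, the E2F site 2.38 and the E-box CACGTG 2.28. The E-box CAGCTG (1.58) and the NHR site (1.26) were also more frequent, but the NHR call was lost in both replicates' own sets (1.23 and 1.15), in the high-signal set (1.09), against flanks (1.07) and away from tRNA, snoRNA and snRNA genes (1.06). Against flanks, 14 of the 16 motif calls were kept, so the NHR call was not the only one lost. The CHR element (0.5), TATA box (0.486), T tract (0.494) and GATA site (0.663) were less frequent, as were the Hox-Pbx site, paired heat shock site, initiator and CCAAT box. Against controls matched on GC content, chosen after the data were examined and run on 2721 of the summits, the GAGA repeat kept an odds ratio of 2.53, the AC repeat 3.30, the E2F site 1.59, CACGTG 1.58, the SP1 site 1.44 and the tRNA B box 15.1. Away from tRNA, snoRNA and snRNA genes the B box had 2.67, also chosen afterwards. With the matched controls the T tract turned to 1.28, the forkhead site newly passed (1.40), and the TATA box (0.970), paired heat shock site (0.951), GATA site (1.08), CHR element (1.05), initiator (1.04), E-box CAGCTG (0.954) and NHR site (1.03) did not pass. Of 2080 6-mers, 944 were more and 606 less frequent, led by GAGAGA and ACGCAG (18.1% against 4%). The GC-matched counts were 428 and 505.

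The loci carried by the transgene gave no excess of peaks. No combined-set summit lay within 20 kb of T26A8.4 (IV 8428957 to 8432893) or of unc-119 (III 10902641 to 10908935). Among 10000 random windows of the same size this was at percentile 22.9 and 21.8. The ranked list held 2 peaks at T26A8.4 and 6 at unc-119, against random medians of 29 and 31.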

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

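The authors' ranked list held 31 peaks at or above the threshold score of 830 that the combined thresholded list leaves out, and these peaks are absent from the combined set used in the report. The tests below were chosen after those 31 peaks were seen. The strongest lay on X from 15810940 to 15811191, with a signal of 1560, which only 2 combined peaks exceed. Of the 31, 11 lay on V and 7 on IV, and 3 overlapped the ribosomal RNA gene rrn-4.2. None overlapped a retained peak. One candidate explanation is a fixed set of regions removed from every list: of 56 past-threshold lines in the other 3 ranked lists at these regions, 100% were left out there too. Soft-masked, repeated sequence made up 64.3% of the windows at the left-out summits and 22.2% at retained summits, a difference of 42.1 percentage points (28.5 to 55.8), so both values are consistent with removal of repeat-rich regions by the authors. What the regions were removed for is not given in the sources used here, and no biological explanation was tested.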

How the results depend on the processing

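The alternatives that used controls matched on GC content, summits away from small RNA genes, 1 summit per interval, the 100 highest-signal peaks, a chance level drawn from a ranked list, and other counts of peaks per set were chosen after the data were examined. Replicate overlap and correlation cannot be run without a replicate. The 50% of peaks with the highest signal numbered 1496, and the sets without a replicate held 1933 and 2141. The ratio for X was 1.35 against gene starts. Matched on GC, 10 motifs and 933 6-mers passed, and the odds ratio was 1.08 for the GATA site, 0.954 for CAGCTG, 1.28 for the T tract, 1.05 for the CHR element and 1.04 for the initiator. The 3′ untranslated ratio turned to 0.914 in the conservative set, 0.442 in the high-signal set, and 0.761 and 0.769 without replicates 1 and 2. The other results with a reversal are given next. Body wall muscle genes gave 0.740 in the conservative set and 0.967 in the narrow window. Germline genes gave 0.853 in the conservative set, 0.723 in the wide window, 0.492 with the nearest gene and 0.903 in the logistic model. lincRNA genes gave 0.846 in the conservative set, 0.905 in the high-signal set, 0.934 and 0.845 without replicates 1 and 2, 0.894 in the narrow window and 0.788 in the wide window. Aminoacyl-tRNA synthetases gave 1.40 in the high-signal set, 1.15 without replicate 1 (0.634 without replicate 2, on the same side as the main value), 1.23 in the narrow window and 1.12 with the nearest gene. Antisense RNA genes gave 1.03 without replicate 2 (0.351 without replicate 1, on the same side as the main value), and ncRNA genes 0.878 with the nearest gene. The forkhead site gave 0.958 in the conservative set and 0.988 away from small RNA genes, and the AP-1 site 0.619 in shorter sequence windows. The cause was not tested.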

Other observations

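The tests of X sequence, of the whole X and of tRNA genes below were chosen after the peak locations had been seen, and so were the genes named in this paragraph. The bound heterochronic genes include lin-14, lin-28, lin-46, lin-66 and mab-10. The 12 bound genes of the 53 in the chromatin list include sdc-2 and dpy-27, components of the X dosage compensation machinery, and no other sdc or dpy gene. The combined set also held 81 intervals with more than 1 summit, 218 summits in all. The widest runs were 11 summits over 3703 bp at pro-1 and mnk-1 (II 10541824 to 10545526) and 9 over 4344 bp at fbxb-72 and icl-1 (V 723650 to 727993).

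Of the 12 X peaks among the 25 highest signals, 11 lie outside promoters. A higher copy number or coverage of the whole X was looked for among the weak peaks, of which 14.4% lay on X, below its 17.7% of genome length. Counts of called peaks do not measure coverage, and the expected share depends on the baseline chosen, so this explanation stays open. The soft-masked share at X summits outside promoters differed from that at random X positions by −11.7 percentage points (−13.7 to −9.65). With the left-out X peaks put back the difference was −11.3. Retained summits of all chromosomes also had a low share, 22.2%, against 30.5% at random X positions outside promoters. Peaks are called only where reads can be placed, which random positions do not require, so this test cannot decide on repeated sequence. For the 11 strongest of the unfiltered ranked list the interval took in 0 (−4.74, −18.8 to 12.7), so repeated sequence stays open for those X peaks too. One hypothesis is that these are recruitment sites of the X dosage compensation complex, whose 12-base motif TCGCGCAGGGAG, taken from background knowledge after the pooled 6-mers had been seen, occurred with up to 2 mismatches at 20 of 363 X summits outside promoters and 16 of 1409 autosomal ones (odds ratio 5.08, 2.60 to 9.90), at 9 of the 11 strongest retained peaks, and at 0.3% of random X positions. The peaks with it had a median signal of 986 and those without 122, so the motif may mark the strong X peaks but not most X peaks, and recovery of such sites with any tagged protein stays open, since no control library was used here.

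The tRNA genes had a bound window in 50.2% of cases. The tRNA genes whose whole sequence has no second exact match were bound in 45 of 140 cases (32.1%, odds ratio 6.24 against protein-coding genes, 4.36 to 8.93). Of those that also had no protein-coding start within 1000 bp, 26 of 99 were bound (26.3%, odds ratio 4.69). Near-identical copies, and peaks of neighbouring tRNA genes inside the window, were not excluded. The test therefore cannot decide whether shared reads are the whole cause. Genes with identical copies were bound more often, in 55.5%, so shared reads could add to the count. Peaks that belong to protein-coding starts within 1000 bp are argued against as the whole cause. Of the 427 tRNA genes with no such start, 200 were bound (46.8%, odds ratio 11.6, 9.52 to 14.1). The promoter window of a start further away can still overlap that of such a tRNA gene, and summits there were not removed. The tRNA genes with a protein-coding start within 1000 bp were bound more often, in 107 of 185 cases (57.8%, odds ratio 18.1), so peaks of neighbouring starts could add to part of the count. Nonspecific recovery of highly transcribed DNA stays open and was not tested, since no control library or other tagged protein was used here. For snoRNA and snRNA genes, neither shared reads, neighbouring protein-coding starts nor nonspecific recovery was tested.

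With upstream intergenic length in a logistic model, 10 of the 10 enriched gene lists kept an odds ratio interval above 1. Nonspecific recovery of highly transcribed genes was not tested for the ribosomal, translation, chaperone and mitochondrial lists either. The number of combined summits near T26A8.4 stood at percentile 22.945 of random windows. Peaks called in replicate 1 alone had a median percentile of 90.3 in the ranked list of replicate 2 (bootstrap interval 88.5 to 92.0, added after the median was seen), with 141 of 635 absent from it.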
